A study of Mus musculus with 30 samples.

How the data were processed

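Total RNA of 30 mouse samples was labelled with Cy5 and hybridised to a whole-genome oligonucleotide array, per the labels. The authors supplied values of 26423 probes in a single table, and these are intensity on a linear scale, deposited as 1 column per sample. Per the series' design text each sample had 2 or 3 replicates (3 in sets 1, 2 and 4, and 2 in sets 3 and 5), so each column appears to be an average, and whether the replicates were separate cultures is not stated. The same text says that the authors normalized 5 sets of samples separately. The values show this: within a set the quantiles of all samples differ by at most 1.45, 1.77, 0.665, 1.91 and 7.32% in sets 1 to 5, and a probe is either present in all samples of a set or in none. The scanner, the software, the background correction and the rule that removed probes are not given in the sources used here. No raw images or single arrays were analysed here.

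Each sample was assigned to a group from its labels. Groups were somatic (7), CiPSC (11), OSKM iPSC (2), SKM-FSK iPSC (2), ESC (5) and days 12, 20 and 32 of treatment (1 each). Of the 26423 probes, 21876 carried 1 gene in the platform annotation, 4547 carried none and 0 carried several, and the gene IDs of 21825 matched the RefSeq table of assembly GRCm38.p6, which also gave the positions printed. Intensities were converted to log2 with the smallest positive value (1e-04) as floor. Where a gene had several probes, the probe measured in most samples, and among those the one with the highest mean, stood for the gene. The part on most samples was added once the missing values had been seen. This left 23629 units, of which 19082 had a gene symbol.

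Comparisons were made with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with group and set as terms fitted to all 30 samples, so that constant differences between sets were removed. The fit also uses the other groups to estimate the sets, so a fitted difference can depart from the difference within a set, most of all where 1 set holds both groups. The p-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison. A gene was called at an adjusted p under 0.05 with a fold change of at least 2. Genes needed values in at least 2 sets that held both groups (1 for SKM-FSK iPSC) and at least 3 residual degrees of freedom, a rule added once the missing values had been seen. Errors given as SE are those of the fitted log2 difference. Numbers of samples given with a comparison are those of its groups, and genes not measured in every set rest on fewer.

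Before the data were examined, the groups, comparisons, alternatives and 28 lists of genes (494 genes, from general knowledge of each lineage or pathway) were fixed. Lists with 5 or more measured members were tested with limma's camera on ranked statistics (cameraPR), with a preset correlation of 0.01 between genes and again with an estimated correlation. This took the place of camera on the values, which does not accept missing values. The adjusted p of a list was taken over the lists of that comparison. In total 221 list tests were run, 59 were called with the preset and 26 with the estimated correlation. Genes were named by a rule fixed in advance: per comparison the 8 largest changes each way among called genes that moved the same way in every set, up to 4 called members of each list described (or up to 2 uncalled as values), and always Pou5f1, Sox2, Klf4, Myc, Nanog, Col1a1, Thy1, Meg3, Rian, Mirg and Dlk1. Genes named outside this rule are said to be so.

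The time course had 1 sample per day and no test. Its differences were taken within set 5 and each list's median was ranked among 10000 random lists matched on mean level in 20 bins (seed 20). Counts of called genes were compared with those of up to 100 other splits of the samples within sets. Similarity to ESC was the Pearson correlation across genes with the ESC of the same set. The precision of all values is limited by the number of arrays.

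Alternatives covered normalization (quantiles within a set, sample medians), a filter on the lowest 25% of genes, the mean of a gene's probes, no set term, only sets holding both groups, each sample and each set left out, the variance prior, an offset at the 5th percentile (13.9), the adjusted p alone, MEF as the only somatic samples, R1 as the only ESC line, a replicate block from the numbers in the titles and Spearman's coefficient. Added later were genes measured in all 5 sets, leaving out the CiPSC lines of set 3, day 12 as reference, a floor of 16 (for the time course and for bounds within set 5), lists over the same genes with and without the CiPSC lines of set 3, and time course genes chosen without set 5.

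The fits were tested on simulated data with the real sets, spreads and missing values, with 100 genes changed by 1 and 100 by 2 on the log2 scale. For CiPSC against somatic (16497 genes) 20% and 75% of these were recovered with 6 false calls, for CiPSC against ESC (16497 genes) 19% and 71% with 5, and for OSKM iPSC against ESC (11406 genes) 6% and 46% with 2. For SKM-FSK iPSC against ESC (16260 genes) the shares were 3% and 27% with 3 false calls, for CiPSC by origin (11406 genes) 21% and 75% with 9, and for CiPSC without T (11406 genes) 10% and 58% with 2. In each of these 6 comparisons 0 random lists were called. The simulated genes varied independently of each other, so this does not test lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.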

Results

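Messenger RNA levels were measured in 30 samples of mouse cells with a 1-colour oligonucleotide array. The starting populations were 7 somatic samples: 4 of mouse embryonic fibroblasts (MEF), 1 of neonatal fibroblasts (MNF), 1 of adult lung fibroblasts (MAF) and 1 of adipose-derived stem cells (ADSC). Chemically induced pluripotent stem cell (CiPSC) lines, made from such cells with small molecules and no added genes, gave 11 samples. Per the labels, the combination of small molecules differed between lines. Induced lines made with transcription factors gave 2 samples (OSKM iPSC), and lines made with 3 factors and the adenylyl cyclase activator forskolin gave 2 more (SKM-FSK iPSC). Embryonic stem cells (ESC) gave 5 samples, 4 of the line R1 and 1 of the line TT2. MEF under chemical treatment were sampled once each at days 12, 20 and 32.

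The samples came in 5 sets, numbered 1 to 5, with 7, 9, 4, 4 and 6 samples. Each set held 1 ESC sample and at least 1 somatic sample. The arrays of sets 1 to 5 reported 13989, 15437, 16339, 21717 and 26397 probes, and 10732 genes were present in all 5 sets. Median intensity per sample lay between 326 and 328 in set 1, 357 and 359 in set 2, 225.1 and 225.3 in set 3, and 346 and 348 in set 4. In set 5 it lay near 110, with 12.8 to 13.7% of values under an intensity of 10. The number of arrays limits the precision. Each sample is 1 column of values that the labels describe as 2 or 3 replicates, so differences between replicates of a sample cannot be seen, and whether the replicates were separate cultures is not stated.

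Every CiPSC line resembled the ESC of its set more than any starting population. Across genes, which are not independent replicates, the Pearson correlation of the 11 CiPSC samples with that ESC ranged from 0.919 to 0.970, against 0.689 to 0.798 for the 7 somatic samples. On average 83.9% ± 5.72 (SD, n = 11) of genes lay within 2-fold of the ESC in CiPSC and 56.2% (32.6 to 63.2%, n = 7) in somatic samples. The OSKM iPSC lines reached 84.0% ± 2.35 (SD, n = 2) and the SKM-FSK iPSC lines 91.8 and 92.8%. All 11 CiPSC samples correlated better with the ESC than with any somatic sample of their set, by Pearson's and by Spearman's coefficient. MEF3, the somatic sample of set 5, had the lowest share, 32.6%. The treated samples of days 12, 20 and 32 also correlated better with the ESC of set 5 than with MEF3. At day 12 Pearson's coefficient was 0.833 with the ESC and 0.810 with MEF3, and Spearman's 0.837 and 0.836. In set 5 this criterion is therefore not met by pluripotent lines alone.

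**Figure D1:**
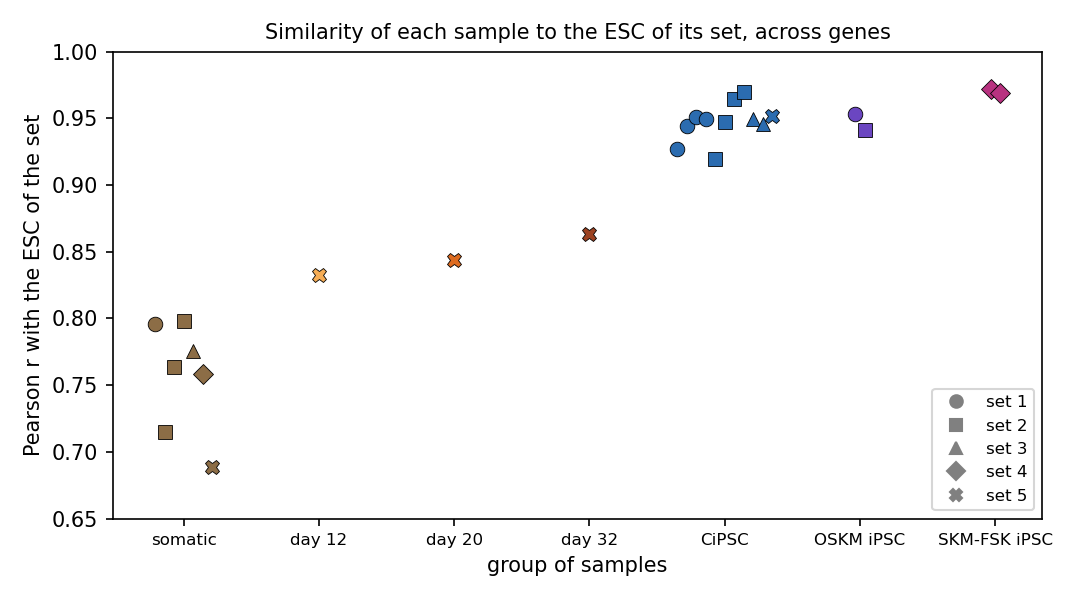
Pearson correlation across genes (no unit) of each sample with the ESC of its set, by group; each point is 1 sample and its shape gives the set. CiPSC lie between 0.919 and 0.970 and somatic samples between 0.689 and 0.798.

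The comparison of CiPSC with somatic samples asked what chemical reprogramming changed. The genes below are the largest changes among called genes that moved the same way in every set. Esrrb, an orphan nuclear receptor of naive pluripotency, rose by 8.64 ± 0.22 on the log2 scale (SE; limma adjusted p = 1.4e-17; 11 CiPSC and 7 somatic samples), and Fgf4, a growth factor of the inner cell mass, by 8.53 ± 0.25. Other large rises were those of Ooep (8.01 ± 0.25), an oocyte and early embryo factor, Mageb16 (7.66 ± 0.48), Qprt (7.45 ± 0.33), an enzyme of NAD synthesis, Zfp42 (7.32 ± 0.33), also called Rex1, Tfcp2l1 (7.32 ± 0.67; 0.36 in set 5), a naive pluripotency factor, and Fam25c (7.16 ± 0.56). MEF3 read 1.8 for Mageb16, whose fitted rise was 6.72 with an offset of 13.9 added to all values. With that offset Qprt (7.21), Tfcp2l1 (6.925), Zfp42 (6.84) and Fam25c (6.78) stood above it. The largest fitted falls were those of Rtl3 (-8.59 ± 1.83), Lrrc17 (-8.59 ± 1.36), Ptn (-8.35 ± 0.56), the growth factor pleiotrophin, Pdgfrb (-7.74 ± 1.58), a receptor of mesenchymal cells, Smoc2 (-7.35 ± 0.67), Dcn (-7.23 ± 0.76), a matrix proteoglycan, Pdgfra (-6.66 ± 0.71) and Eid1 (-6.51 ± 2.27). Of these falls, the folds of 4 rest most on values too low to read, since the CiPSC control line read 0.1 for Rtl3 and Eid1 and 0.8 for Lrrc17 and Pdgfrb. With values under 16 set to 16, they fell within set 5 by at least 7.30 (Rtl3), 7.39 (Lrrc17), 7.89 (Pdgfrb) and 6.78 (Eid1), and the differences within set 3 were -4.48, -6.12, -4.18 and -1.45. With an offset of 13.9 added to all values the fitted differences were -5.79, -6.80, -5.81 and -3.88, all still called, against -8.04 for Ptn, so the order of the falls depends on the floor. Without MEF3 too few sets are left to test these 4. The call of Eid1 was lost without CiPS45 (adjusted p = 0.0503), CiPS WT1 (0.0621) or CiPS WT2 (0.0611). Smoc2 and Pdgfra also read under 16 in the CiPSC control line, at 10.8 and 13.1. Their differences within set 5 were -7.93 and -6.94, and -7.37 and -6.65 with values under 16 set to 16.

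Of the 22 pluripotency genes measured of the 33 fixed, 22 rose and 0 fell, and 22 rose when adjusted over the list alone (list adjusted p = 1.7e-17; median 3.68). Sox2 rose by 5.20 ± 0.85 (6.02 and 6.68 in sets 1 and 3 and 0.54 in set 5, where its probe could not be read; 6.64 without set 5), Nanog by 3.50 ± 0.82, Pou5f1 by 2.31 ± 0.41 and Klf4 by 1.85 ± 0.41, while the log2 difference of Myc was 0.29 ± 0.96 (adjusted p = 0.831). Pou5f1, which encodes Oct4, was higher in CiPSC in sets 1, 2 and 3 and lower in set 5, where its probe read 24.2 in the CiPSC control line and 61.0 in MEF3. Of 26 fibroblast genes, 22 fell and 4 did not pass, the same count as adjusted over the list alone (list adjusted p = 1.2e-09), with S100a4 at -6.36 ± 0.64, Col6a1 at -5.67 ± 0.42 and Thy1, a fibroblast surface antigen, at -5.09 ± 0.57. Of 19 Hox and body pattern genes, which hold positional identity, 15 fell and 4 did not pass (15 over the list alone; adjusted p = 7.2e-07), among them Hoxc6 (-4.14 ± 0.68) and Hoxc8 (-3.58 ± 0.57).

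Germline genes, many of them silenced by promoter methylation in somatic cells, rose in 10 of 15 cases with 5 not passing (10 over the list alone; adjusted p = 7.2e-07), led by Rhox5 (7.02 ± 0.36), Dazl (5.53 ± 0.31) and Piwil2 (4.66 ± 0.33). Of 9 genes of DNA methylation and its removal, 6 rose and 3 did not pass (6 over the list alone; adjusted p = 0.00152), with the dioxygenase Tet1 at 5.62 ± 0.36, Dnmt3b at 4.42 ± 0.37 and Dnmt3l at 4.30 ± 0.52. Of 11 polycomb and H3K9 genes, 9 rose and 2 did not pass (9 over the list alone; adjusted p = 7.2e-07), with Mtf2 at 3.74 ± 0.38, Jarid2 at 3.35 ± 0.29 and the methyltransferase Ezh2 at 2.70 ± 0.38. Of 23 cell cycle genes, 17 rose and 6 did not pass (17 over the list alone; adjusted p = 3.0e-10), with the replication helicase subunits Mcm2 at 2.79 ± 0.28 and Mcm3 at 2.66 ± 0.20. These 4 lists and the pluripotency, fibroblast and Hox lists were also called with an estimated correlation, at adjusted p from 3.7e-04 to 0.0401.

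Calls of 8 further lists were lost with an estimated correlation. Of 17 epithelial genes 11 rose and 6 did not pass (11 over the list alone; adjusted p = 4.6e-05; adjusted p = 0.151 with an estimated correlation), among them Epcam (3.90 ± 0.36) and Cdh1 (4.00 ± 0.82), which encodes E-cadherin. Of 13 genes of primed pluripotency 10 rose, 1 fell and 2 did not pass (10 and 1 over the list alone; adjusted p = 3.6e-04; adjusted p = 0.134 with an estimated correlation). Of 14 TGF-beta targets 10 fell, 1 rose and 3 did not pass (10 and 1 over the list alone; adjusted p = 0.00160; adjusted p = 0.0607 with an estimated correlation), with Ltbp2 at -4.74 ± 0.56 and Tgfb1i1 at -4.54 ± 0.38. Of 18 interferon-stimulated genes 10 fell, 1 rose and 7 did not pass (12 and 1 over the list alone; adjusted p = 3.0e-04; adjusted p = 0.134 with an estimated correlation), with Irf7 at -5.09 ± 0.43 and Gbp2 at -2.72 ± 0.43. Of 10 macrophage genes 6 fell, 1 rose and 3 did not pass (6 and 1 over the list alone; adjusted p = 0.00367; adjusted p = 0.336 with an estimated correlation), with the complement genes C1qa at -5.94 ± 0.38 and C1qc at -3.73 ± 0.48.

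The remaining 3 of those 8 lists also depended on single samples. Of 17 extraembryonic endoderm (XEN) genes 8 fell, 3 rose and 6 did not pass (8 and 3 over the list alone; adjusted p = 0.0379; adjusted p = 0.316 with an estimated correlation). The falling members Plat (-3.85 ± 0.35), a plasminogen activator, Fst (-3.67 ± 0.78) and Col4a2 (-3.29 ± 0.28) are also made by fibroblasts. Of 14 glycolysis genes 4 rose and 10 did not pass (4 over the list alone; adjusted p = 0.0188; adjusted p = 0.375 with an estimated correlation), with the kinases Hk2 at 1.98 ± 0.32 and Pfkm at 1.61 ± 0.26. Of 8 adipogenic genes 2 fell, Lpl (-2.10 ± 0.47) and Cebpa (-1.41 ± 0.30), and 6 did not pass (2 over the list alone; adjusted p = 0.0355; adjusted p = 0.134 with an estimated correlation). Without MEF3 the adjusted p was 0.145, 0.132 and 0.0974 for the XEN, glycolysis and adipogenic lists, and without the CiPSC control line it was 0.104, 0.0775 and 0.0619. Without WT MEF it was 0.0580 for the XEN list and 0.0993 for the glycolysis list.

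The other 10 lists did not pass, at adjusted p from 0.0549 to 0.616. Members rose and fell in numbers of 4 and 0 of 8 for trophoblast genes, 1 and 0 of 5 for genes of the 2-cell stage, 5 and 8 of 23 for imprinted genes outside the Dlk1-Dio3 region, and 5 and 2 of 15 for p53 and senescence genes. The numbers were 1 and 3 of 11 for cAMP targets, 0 and 2 of 8 for Wnt targets, 4 and 1 of 11 for neural genes, 1 and 2 of 10 for mesoderm and muscle genes, 1 and 3 of 10 for endothelial genes and 2 and 1 of 10 for housekeeping genes. The neural list had a median of -0.15 beside a mean of 0.44. The trophoblast list passed without CiPS21 (adjusted p = 0.0499), CiPS WT2 (0.0442), MEF2 (0.0447), MEF3 (0.0197) or the CiPSC control line (0.0273). In the imprinted Dlk1-Dio3 region, whose noncoding RNA Meg3 is silenced in some induced lines, Meg3 differed by -0.86 ± 0.29 between CiPSC and somatic samples, under 2-fold, and by -1.03 without MAF. Dlk1 differed by -1.67 ± 1.03 (adjusted p = 0.211), with 1.24 in set 2 and -5.56 and -4.88 in sets 3 and 5. Against ESC, Meg3 differed by 0.11 ± 0.33 in CiPSC and by 0.05 ± 0.50 in OSKM iPSC. Rian and Mirg had no named probe, and Col1a1 could not be tested.

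In total 4624 of 16497 genes were called between CiPSC and somatic samples, 2435 higher and 2189 lower in CiPSC, and 3944 of them went the same way in every set that held both groups. Tests treat each sample as 1 value.

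**Figure D2:**
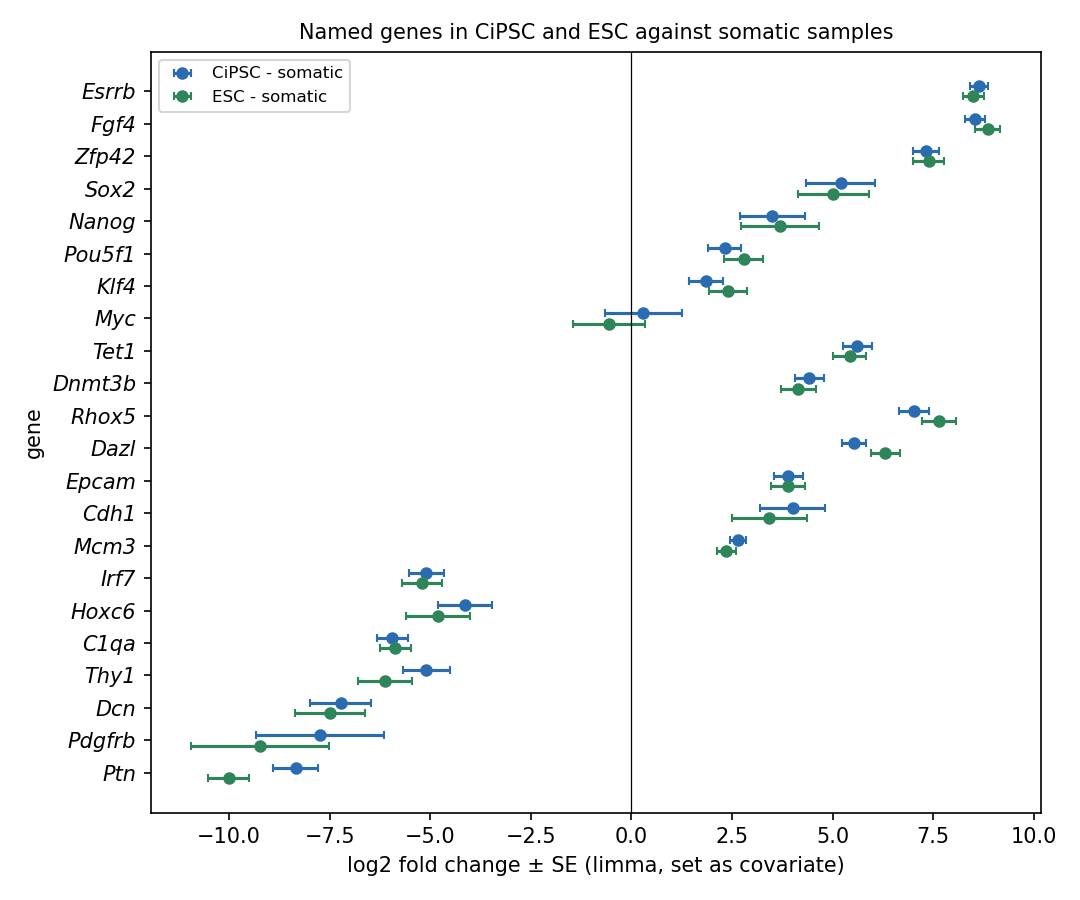
Log2 fold change with its SE (limma) of named genes in 11 CiPSC (blue) and 5 ESC samples (green) against 7 somatic samples. Genes not measured in every set, such as Ptn and Myc, rest on fewer samples. Esrrb lies at 8.64 and 8.50, and Ptn at -8.35 and -10.01, while the intervals of Myc include 0.

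The comparison of ESC with somatic samples gave the reference difference. The groups held 5 ESC and 7 somatic samples, and genes not measured in every set rest on fewer. Fgf4 rose by 8.86 ± 0.31 in ESC (SE), Esrrb by 8.50 ± 0.26, Mageb16 by 7.79 ± 0.57 (6.78 with the offset, since MEF3 read 1.8), the homeobox gene Rhox5 by 7.65 ± 0.43, Zfp42 by 7.38 ± 0.39 and the uridine phosphorylase Upp1 by 7.30 ± 0.75. Ptn (-10.01 ± 0.52, and -9.23 with the offset, since ESC5 read 6.25), Pdgfrb (-9.22 ± 1.72, and -6.97 with the offset, since ESC5 read 0.7), Smoc2 (-8.44 ± 0.63), the mesenchymal homeobox gene Prrx1 (-7.94 ± 0.79), Col6a3 (-7.93 ± 0.80) and Dcn (-7.50 ± 0.87) fell. Sox2 rose by 5.01 ± 0.88 (0.28 in set 5), Pou5f1 by 2.79 ± 0.48, Klf4 by 2.40 ± 0.47 and Nanog by 3.69 ± 0.97. Dlk1 fell by 3.95 ± 1.18, with a difference of the other sign in set 2 (1.27), and the difference of Myc was -0.56 ± 0.89. Without ESC2 the adjusted p of Nanog was 0.0517. The Dlk1 call was lost without MEF2 or ESC4 (adjusted p = 0.0733) or ESC5 (0.0674), and Myc passed without MEF3 (-1.95, adjusted p = 0.0295).

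Fixed lists moved in ESC as follows. Pluripotency genes rose in 21 of 22 cases (21 over the list alone; adjusted p = 1.7e-16) and fibroblast genes fell in 25 of 26 (25 over the list alone; adjusted p = 2.2e-13), with a median of -5.14. TGF-beta targets, which include smooth muscle genes, fell in 10 of 14 cases (10 fell and 1 rose over the list alone; adjusted p = 1.1e-04), with Tagln at -7.00 ± 0.90 and Acta2 at -5.96 ± 0.75. Germline genes rose in 10 of 15 (10 over the list alone; adjusted p = 6.0e-07), with Dazl at 6.31 ± 0.35. Cell cycle genes rose in 14 of 23 (15 over the list alone; adjusted p = 1.5e-08), polycomb and H3K9 genes in 9 of 11 (9 over the list alone; adjusted p = 7.0e-06), and DNA methylation genes in 6 of 9 with 1 falling (the same over the list alone; adjusted p = 0.00540), with Tet1 at 5.42 ± 0.41. Hox genes fell in 15 of 19 (15 over the list alone; adjusted p = 1.2e-06). These 8 of the 13 called lists were also called with an estimated correlation, at adjusted p from 0.00185 to 0.0430, and the epithelial, primed pluripotency, interferon, glycolysis and macrophage lists were not, at adjusted p from 0.150 to 0.338 with an estimated correlation. In total 4838 of 16509 genes were called, 2487 higher and 2351 lower in ESC.

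Changes in CiPSC and ESC against somatic samples overlapped. Of 16497 genes tested in both, 2044 were called higher in both, 1882 lower in both and 0 in opposite directions, where lists of the same sizes drawn independently would share 367 and 312; at an unadjusted p under 0.05 limma passed 7841 and 7469 genes in the CiPSC and the ESC comparison. Both use the same somatic samples, so part of the agreement comes from them. In 20 simulations of unchanged groups with shared somatic samples 0 genes were shared, and the log2 differences correlated at 0.454 across genes (covariance 0.0919), against 0.953 (covariance 1.77) in the data. With the somatic samples divided, 4 for CiPSC and 3 for ESC, 1497 genes were higher in both, 1400 lower in both and 4 opposite among 13935 genes, with a correlation of 0.840 and a covariance of 1.62. Genes are not independent replicates.

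The comparison of CiPSC with ESC asked how the chemical lines differ from embryonic stem cells. Just 5 genes passed, all higher in CiPSC, and no fixed pluripotency gene passed. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines (chromosome 17, 37193892 to 37196101), was higher by 4.13 ± 0.57 (SE; limma adjusted p = 0.0042). Tmem245 (chromosome 4, 56876003 to 56947455) was higher by 2.58 ± 0.44 (adjusted p = 0.026), S100a11, a calcium-binding protein (chromosome 3, 93520496 to 93526288), by 1.93 ± 0.27 (0.024), Gipc2 (chromosome 3, 152093839 to 152165900) by 1.75 ± 0.30 (0.026), and Gemin7, a subunit of the complex that assembles spliceosomal particles (chromosome 7, 19564949 to 19573343), by 1.62 ± 0.25 (0.015). Tmem245 fell outside the rule for named genes, since its difference in set 2 was -0.06, and it was named after its values were seen. The ESC of set 2 is the line TT2, and there the other measured genes differed least: Ubd by 0.90 in set 2 and by 4.07 to 5.78 in the others, Gipc2 by 0.66 against 1.74 to 2.66, and Gemin7 by 0.92 against 1.80 to 2.11.

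Across all 16497 genes 819 had an unadjusted p under 0.05, where chance alone gives 825. The count of 5 depended on single ESC and CiPSC samples: it was 0 without ESC1, 51 without the TT2 sample ESC2, 1 without ESC3, 2 without ESC4 or ESC5, 3 without CiPS34 or the CiPSC control line, 9 without ADSC CiPS2, and 2 without CiPS WT1 or CiPS WT2. Without set 5 the count was 5, 3 higher and 2 lower, and just 2 of the 5 genes above, Ubd and Gemin7, were among them. Ubd did not pass without ESC1 (adjusted p = 0.138), and Gemin7 without ESC1 (0.240), ESC3 (0.146) or ESC5 (0.0507). S100a11 did not pass without ESC1 (0.291), ESC3 (0.0674), ESC4 (0.0746), ESC5 (0.0715), CiPS WT1 (0.0713), CiPS WT2 (0.0709) or the CiPSC control line (0.0701). Tmem245 did not pass without any of those 7 samples (at most 0.291) or CiPS34 (0.0542), nor did Gipc2 without any of them (at most 0.287), CiPS34 (0.0542) or CiPS45 (0.0540). Ifitm3 passed without ADSC CiPS2 (0.00921). With R1 as the only ESC line, 22 genes were higher and 29 lower in CiPSC. They included Ifitm3 (1.64), a membrane protein induced by interferon, on the higher side and Xaf1 (-3.66), an apoptosis regulator, and Nr5a2 (-2.47), a nuclear receptor active in pluripotent cells, on the lower side, named after their values were seen.

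**Figure D3:**
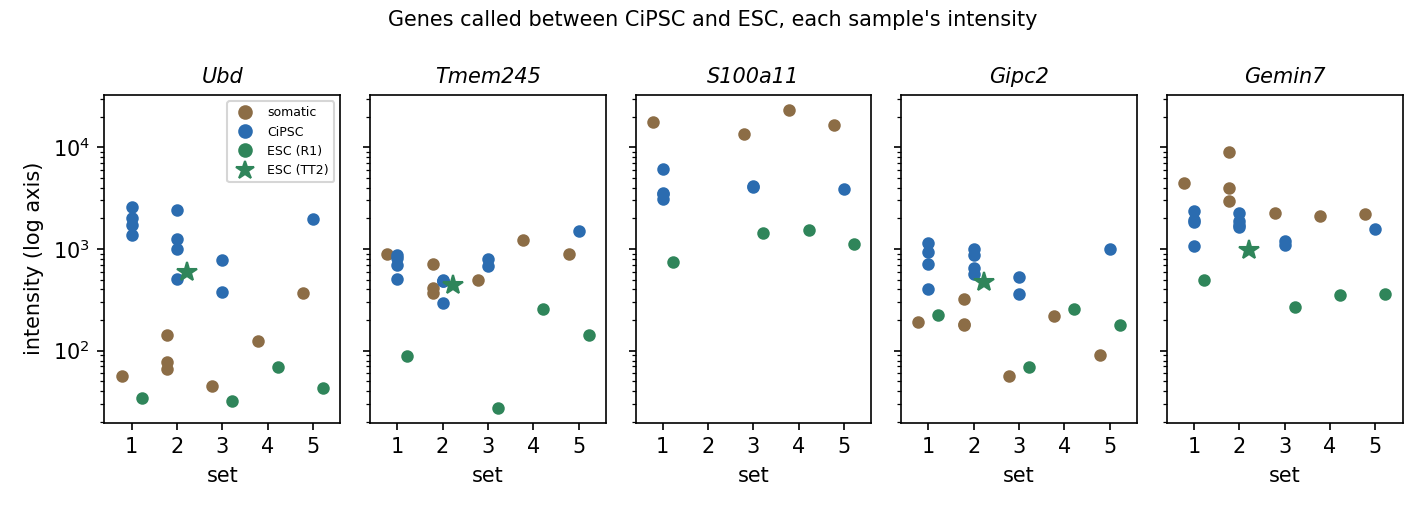
Intensity (log axis) of the 5 genes called between CiPSC and ESC in each somatic, CiPSC and ESC sample of sets 1 to 5; stars mark the ESC sample of line TT2, and S100a11 was not measured in set 2. Ubd reads 598 in the TT2 sample and 32.1 to 68.6 in the R1 samples.

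As a group, fibroblast genes stood higher in CiPSC than in ESC (median 0.80 over 26 genes; adjusted p = 1.8e-09; adjusted p = 0.125 with an estimated correlation), although 0 of 26 passed alone over all genes and 3 rose when adjusted over the list alone. TGF-beta targets stood higher as well (median 0.80 over 14 genes, 0 called and 2 over the list alone; adjusted p = 6.3e-05; adjusted p = 0.0410 with an estimated correlation). These lists are not independent, since they share members such as Acta2, which differed by 3.24. The fibroblast shift moved with the set 3 lines: medians against the ESC of the set were 2.19 in CiPS WT1 and 2.46 in CiPS WT2 and lay between -0.13 and 0.91 in the other 9 CiPSC lines. Without those lines fewer members could be tested, 17 fibroblast genes and 12 TGF-beta targets. Over these same genes the medians were 0.49 with the lines (adjusted p = 0.00408) and 0.24 without (adjusted p = 0.435) for fibroblast genes, and 0.60 (adjusted p = 0.00591) and 0.57 (adjusted p = 0.153) for TGF-beta targets, and without ESC3 the adjusted p of the fibroblast list was 0.127. Over the same genes without the lines, the median of imprinted genes went from 0.37 (adjusted p = 0.00945) to 0.47 (0.00289) and that of glycolysis genes from -0.22 (0.549) to -0.54 (adjusted p = 0.0133; adjusted p = 0.666 with an estimated correlation). Imprinted genes outside the Dlk1-Dio3 region had a median of 0.34 (0 of 23 called, 0 over the list alone; adjusted p = 0.0335; adjusted p = 0.997 with an estimated correlation), a call lost without CiPS34 (adjusted p = 0.0732), MAF CiPS3 (0.0889), ADSC CiPS2 (0.157), ESC1 (0.384) or ESC4 (0.406). The pluripotency list had a median of 0.11 (0 of 22 called; 1 rose and 1 fell over the list alone; adjusted p = 0.996).

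**Figure D4:**
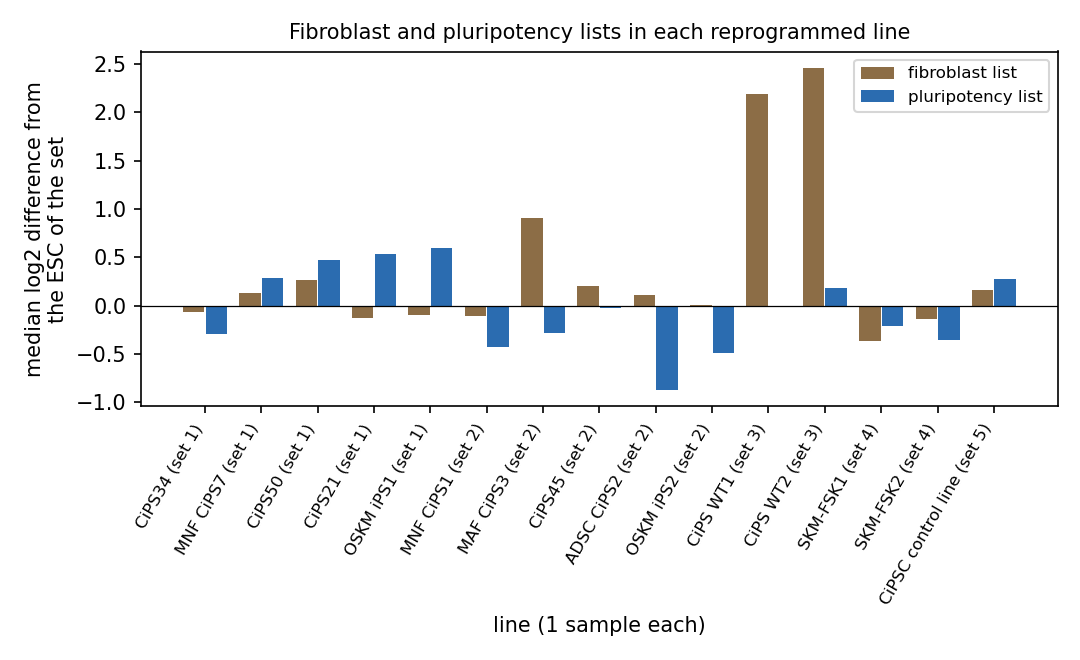
Median log2 difference of the fibroblast (brown) and pluripotency (blue) lists from the ESC of the set, for each reprogrammed line, 1 sample per bar. The fibroblast bars of CiPS WT1 and CiPS WT2 reach 2.19 and 2.46.

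Lines made with transcription factors gave a second reference. OSKM iPSC (2 samples) differed from ESC (5 samples, 2 of them in the same sets) in 2 of 11406 genes, Flywch2 (3.91 ± 0.57; limma adjusted p = 0.0070; chromosome 17, 23776914 to 23786216) and Gemin7 (2.43 ± 0.39; adjusted p = 0.013), both higher, with 672 genes at an unadjusted p under 0.05. Neither passed without 1 of the OSKM lines: the adjusted p of Flywch2 was 0.312 without OSKM iPS1 and 0.221 without OSKM iPS2, and that of Gemin7 0.286 and 0.747. Gemin7 also did not pass without ESC1 (adjusted p = 0.0833). The count was 0 without OSKM iPS2, 1 (another gene) without OSKM iPS1 and 8 without ESC2. None of the 24 lists tested passed, but the cell cycle list did so without ESC1 (0.0151) or OSKM iPS2 (0.00303). Between CiPSC and OSKM iPSC limma called 0 of 11406 genes, with 630 at an unadjusted p under 0.05 where chance gives 570. The count was 1 without CiPS21 or OSKM iPS1. Cell cycle genes had a median of 0.31 toward CiPSC (0 of 20 called, 0 over the list alone; adjusted p = 0.0029; adjusted p = 0.879 with an estimated correlation), which was lost without OSKM iPS1 (adjusted p = 0.549).

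SKM-FSK iPSC, made from MEF with 3 factors and forskolin, were compared with somatic samples; whether their changes differ from those of CiPSC was not tested. Fbxo15, an embryonic F-box gene, rose by 8.60 ± 1.84 (SE; 2 SKM-FSK and 7 somatic samples, 1 of them in the same set), Rhox5 by 8.50 ± 0.75, Upp1 by 8.36 ± 1.31, Esrrb by 8.10 ± 0.46, Qprt by 7.75 ± 0.69 and the germ cell RNA-binding protein gene Dazl by 7.50 ± 0.56. Ptn (-11.02 ± 0.68), the collagen gene Col1a2 (-8.99 ± 1.68), Dcn (-8.89 ± 1.39), Smoc2 (-8.62 ± 0.83), Ccn4 (-8.32 ± 0.74) and Prrx1 (-8.32 ± 1.05) fell. Sox2, a factor supplied to these lines per their name, rose by 6.53 ± 1.32, Nanog by 5.70 ± 1.55 and Pou5f1, not supplied, by 3.29 ± 0.85, while Myc fell by 4.43 ± 1.18 and Thy1 by 7.36 ± 1.18. Klf4 differed by 1.61 ± 0.76 and did not pass. The calls of Nanog and Pou5f1 were lost without either line, at adjusted p of 0.0838 and 0.0731 without SKM-FSK1 and 0.0901 and 0.0595 without SKM-FSK2. That of Myc was lost without SKM-FSK1 (0.158), SKM-FSK2 (0.120) or WT MEF (0.0572).

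Pluripotency genes rose in 15 of 21 cases (18 over the list alone; adjusted p = 2.1e-15), germline genes in 9 of 15 (10 over the list alone; 1.5e-09), cell cycle genes in 13 of 23 (17 over the list alone; 9.4e-11), polycomb and H3K9 genes in 7 of 11 (8 over the list alone; 2.8e-05) and DNA methylation genes in 4 of 9 (4 over the list alone; 0.00619). Fibroblast genes fell in 22 of 25 cases (22 over the list alone; adjusted p = 1.0e-18), interferon genes in 9 of 18 (10 over the list alone; 1.0e-06), TGF-beta targets in 9 of 14 (10 fell and 1 rose over the list alone; 2.0e-05) and Hox genes in 6 of 19 (9 over the list alone; 3.5e-06). These 9 of the 16 called lists were also called with an estimated correlation, at adjusted p from 0.00198 to 0.0314, and the epithelial, XEN, primed pluripotency, imprinted, glycolysis, Wnt and macrophage lists were not, at adjusted p from 0.109 to 0.318 with an estimated correlation. The Wnt call was lost without MEF3 (adjusted p = 0.0637). In total 2475 of 16260 genes were called, 1187 higher and 1288 lower. The count was 1100 without SKM-FSK1 and 1079 without SKM-FSK2.

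Against ESC, SKM-FSK iPSC differed in 1 of 16260 genes, Iqcg (-6.67 ± 0.78; limma adjusted p = 0.0010; chromosome 16, 33014270 to 33057145). At an unadjusted p under 0.05 limma passed 416 genes, where chance gives 813. In the simulated data this comparison recovered 27% of changes of 2 on the log2 scale, so the low count does not show that the lines equal ESC. Iqcg read 16381 in ESC4 and 6051 in MEF2, 110 and 136 in the SKM-FSK lines and between 0.1 and 124 in every sample of sets 1, 2 and 5; without a set term its difference was 1.22 (adjusted p = 0.818). Wnt targets stood lower (median -0.87 over 8 genes, 0 called, 0 over the list alone; adjusted p = 0.0015; adjusted p = 0.0352 with an estimated correlation). Fibroblast (median -0.79), interferon (-0.95) and imprinted genes (-0.45) stood lower and germline (0.85), cell cycle (0.28) and glycolysis genes (0.33) higher, with 0 members called over all genes, at adjusted p from 6.7e-04 to 0.0210, and at adjusted p from 0.394 to 0.658 with an estimated correlation. Over the list alone 1 germline and 1 cell cycle gene rose. These medians are of fitted values, which lean on other sets. Within set 4, the only set with both groups, the medians were -0.72 for Wnt, 0.83 for germline, 0.23 for cell cycle and 0.32 for glycolysis genes, but -0.22 for fibroblast, 0.00 for interferon and 0.09 for imprinted genes. The glycolysis call was lost without ESC2 (adjusted p = 0.0753) or ESC3 (0.0787).

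Within CiPSC, cell of origin and the compound T, the demethylase inhibitor tranylcypromine, were compared in sets 1 and 2. Of 4 lines of MNF, MAF or ADSC origin and 7 of MEF origin, 4 and 4 lie in those sets, and limma called 0 of 11406 genes, with 239 at an unadjusted p under 0.05 where chance gives 570. The count was 1 without MNF CiPS7. Glycolysis genes had a median of -0.37 in lines of other origin, with -0.52 in set 1 and 0.03 in set 2 (0 of 7 called, 0 over the list alone; adjusted p = 0.0451; adjusted p = 0.384 with an estimated correlation), lost without MNF CiPS7 (adjusted p = 0.173), ADSC CiPS2 (0.239), CiPS21 (0.0963) or CiPS WT2 (0.0758). The origin of 1 line, ADSC CiPS2, is given in different ways by its labels. Each CiPSC line of sets 1 and 2 also had its own combination of compounds, so origin and compounds cannot be told apart. Of 2 lines made without T, CiPS50 and CiPS45, and 9 made with it, 2 and 6 lie in those sets, and limma called 0 of 11406 genes, with 182 at an unadjusted p under 0.05, and 1 gene without CiPS45. Pluripotency genes had a median of 0.48 without T (adjusted p = 3.0e-04; adjusted p = 0.585 with an estimated correlation), primed pluripotency genes 0.43 (0.0431; adjusted p = 0.585 with an estimated correlation) and XEN genes -0.51 (0.00875; adjusted p = 0.283 with an estimated correlation), each with 0 genes called, also over the list alone. All 3 were lost without CiPS45, at adjusted p of 0.187, 0.874 and 0.156, the XEN call also without CiPS50 (0.121) and the primed pluripotency call also without MNF CiPS1 (0.123), CiPS WT2 (0.0528) or the CiPSC control line (0.202), and CiPS45 is also the sole MEF-derived line of set 2. CiPS45 was made without valproic acid (V) as well, which all 9 lines made with T received, so for this line the effects of T and V cannot be separated.

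The chemical time course in set 5 was followed in 1 sample per day, so these are differences without a test. Probes of the same gene also followed each other less in this set: over 689 genes with 2 probes the difference of ESC and MEF correlated between probes at 0.183, against 0.431 to 0.743 in sets 1, 3 and 4, that of days 32 and 12 at 0.427 and that of days 20 and 12 at 0.256. Per the labels, a further compound, Z, was part of the treatment at days 20 and 32 but not at day 12. Differences between day 12 and the later days therefore cannot separate time from Z. Markers of extraembryonic endoderm, which lines the yolk sac, stood higher at the later days and low again in the CiPSC control line. Gata4, a regulator of that lineage, read an intensity of 609 at day 12, 2769 at day 20 and 7183 at day 32, and 386 in the CiPSC line. Gata6 read 2265, 5187 and 12003 and then 261, and the transport protein gene Ttr 94.2, 1243 and 2407 and then 33.8. Sox17 read 309, 353 and 222 and then 1091. The XEN list stood 0.80 (median log2, 25 genes) higher at day 32 than at day 12, above 100% of 10000 random lists of matched level. Against MEF3 its medians were -0.46, 0.60 and 0.63 at days 12, 20 and 32, and -1.16 in the CiPSC line.

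Some genes of pluripotent and germ cells stood higher at day 32 while others did not. Rhox5 read 402, 1174 and 17418 at days 12, 20 and 32 and 18342 in the CiPSC line. Esrrb read 48.2, 97.2 and 1125 against 25958 in the CiPSC line, and the Nodal coreceptor gene Tdgf1 56.8, 77.0 and 1032 against 42519. Nanog read 156, 122 and 89.4 against 2373. The probes of Sox2, Sall4 and Dppa2 read at most 34.2 in ESC5 and 41.1 in the CiPSC line, so their course cannot be read. The pluripotency list had medians against MEF3 of -0.58, -0.05 and 0.33 at days 12, 20 and 32, and of 1.49 in the CiPSC line. Between days 12 and 32 its median difference was 0.44 (99.9th percentile of random lists), that of the epithelial list 1.21 and that of the cell cycle list 1.48 (both the 100th percentile), with Epcam at 120, 387 and 1087 and the kinetochore protein gene Cenpa at 2421, 7069 and 13015. The germline list differed by 0.32 (97.0th percentile) and the interferon list by 0.60 (99.9th). Fibroblast genes differed from MEF3 by 0.72 (97.3th percentile), 0.29 and -0.37 at days 12, 20 and 32 and by -3.85 in the CiPSC line, and by -0.58 (0.04th percentile) from day 12 to day 32.

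**Figure D5:**
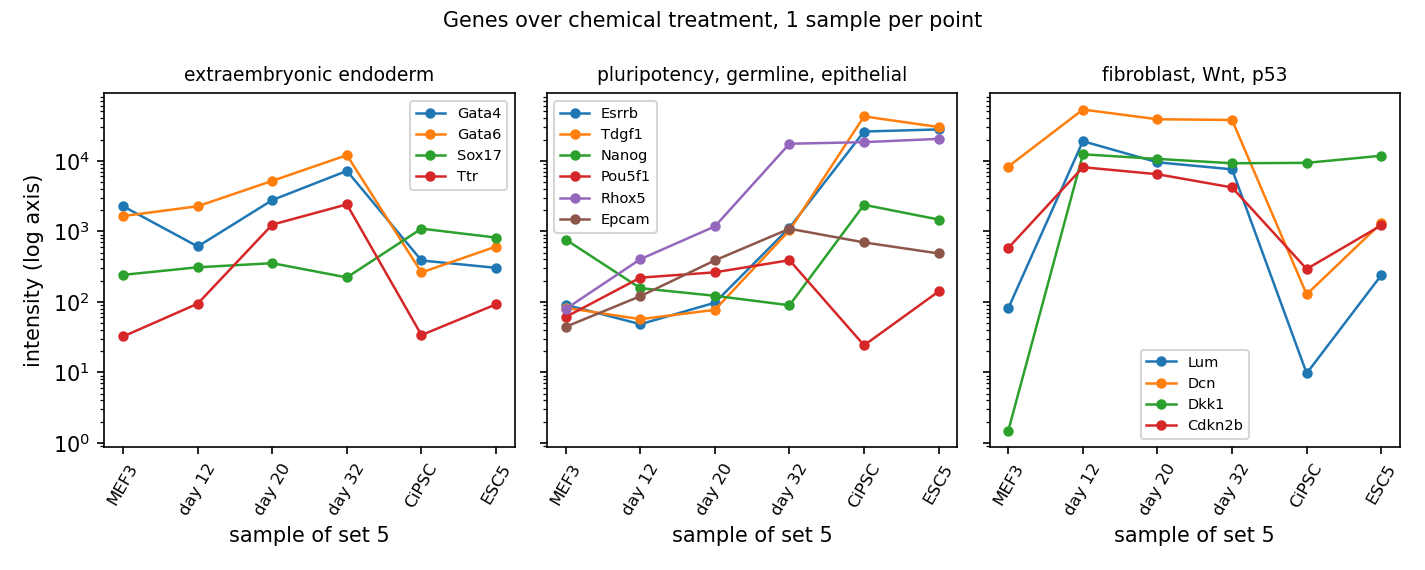
Intensity (log axis) of named genes in the 6 samples of set 5, 1 sample per point, in the order of treatment with the CiPSC control line and ESC5 last. Gata4, Gata6 and Ttr are highest at day 32, and Esrrb and Tdgf1 in the CiPSC line and ESC5.

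At day 12 other lists already differed from MEF3. Genes of p53 and senescence stood 1.95 higher (median, 100th percentile), with the cell cycle inhibitor gene Cdkn2b, also on the TGF-beta list, at 8094 against 581 and Pmaip1 at 5036 against 78.2. Wnt targets stood 1.73 higher (99.9th percentile), with the Wnt inhibitor gene Dkk1 at 12337 against 1.5 and Apcdd1 at 5372 against 104; the treatment included an inhibitor of the Wnt pathway kinase GSK3. Targets of cAMP stood 1.21 higher (98.9th percentile), with Ptgs2 at 4325 against 234; the treatment included forskolin. Macrophage genes stood lower (-1.63, 0.09th percentile), with the complement gene C1qb at 9.1 against 1074, and so did cell cycle genes (-1.81, 0th percentile). All of these rest on MEF3, whose values stand apart from the other MEF. Counts over 2-fold against MEF3 were 3930 higher and 4753 lower of 13755 genes at day 12, 4041 and 4893 of 13852 at day 20, and 4599 and 5193 of 14256 at day 32. Between days 12 and 32, 1443 of 12599 genes stood more than 2-fold higher and 1634 lower.

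Genes called between ESC and somatic samples in sets 1 to 4, chosen without set 5, were also followed. Of 2479 called higher there, 23.8, 26.5 and 33.7% were more than 2-fold above MEF3 at days 12, 20 and 32, against 23.8, 24.4 and 26.9% of all 16385 genes. Of 2406 called lower, 20.4, 22.2 and 25.6% were more than 2-fold below MEF3, against 32.2, 33.6 and 36.7% of all genes. From day 12 to day 32, which does not involve MEF3, 21.8% of the genes called higher rose more than 2-fold, against 9.22% of all genes, and 14.6% of those called lower fell more than 2-fold, against 12.4%. The correlation with ESC5 across genes was 0.833, 0.843 and 0.864 at days 12, 20 and 32, and 0.952 in the CiPSC control line.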

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

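The tests of another MEF population, of bright genes in MEF3, of genes well above the floor in set 5 and of cells with the profile of the set 3 MEF were chosen only after the result was seen. An extreme sample was marked where its gap from the nearest other value was a large share of the group's range, a rule that chance meets in about 1 in 20 groups; 16 groups were tested and 4 met it. MEF3 lay apart from the other somatic samples, with 32.62% of genes within 2-fold of the ESC of its set (the nearest other sample had 52.7%, the highest 63.2%). In the same set the median ESC minus somatic difference of the pluripotency list was 1.21 (4.21 to 5.34 in the others) and that of the housekeeping list 1.49 (0.14 to 0.52 in the others). Dlk1 differed by 1.267 between ESC and somatic samples in set 2, where the other sets gave -6.51 to -7.58. Set 2 holds no MEF, and its somatic samples are MNF, MAF and ADSC. Fitted as a group of its own, TT2 stood 4.22 above R1 for Ubd, 3.12 for Tmem245, 1.10 for Gipc2 and 0.75 for Gemin7. These genes are among the 5 called between CiPSC and ESC. Only effect sizes are given, since TT2 is 1 sample.

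The first pattern is that MEF3 stands apart. Gains of single probes may account for part of it: in genes with 2 probes, the deviations of MEF3 from the other MEF correlated between probes at 0.1462, against 0.476 to 0.655 for the ESC of sets 1 to 4, but the other samples of set 5 (0.194 to 0.255) and MNF of set 2 (0.212) were low as well, so the value is not particular to MEF3. Within set 5, ESC5 minus MEF3 gave 0.183 and ESC5 minus the treated samples 0.340 to 0.366. Signal near the floor as the whole cause is argued against: over the brightest genes stable in sets 1 to 4, MEF3 correlated with the mean of those sets at 0.4605 (0.662 to 0.717 in the rest of set 5, 0.825 to 0.953 in sets 1 to 4), and over the 974 of these that read at least 64 throughout set 5 at 0.477 against 0.760 to 0.868 in the rest of the set (gap -0.284, bootstrap 95% interval -0.325 to -0.244), while the share of bright genes within 2-fold of the ESC, 42.12% (40.6 to 43.6%) against 48.2 to 59.3% in other somatic samples, lay too near its bound to decide alone. Another MEF population or culture state stays open, since over all stable genes MEF3 gave 0.6082 but the rest of set 5 (0.820 to 0.845) also lay under sets 1 to 4 (0.949 to 0.986).

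The second pattern is that fibroblast genes stand higher in both CiPSC lines of set 3. Quantile normalization within the set left the list's medians at 2.193 and 2.47 above the ESC, and the housekeeping medians at 0.28 and -0.03. As deposited the list's medians were 2.188 and 2.464. The deposited quantiles of this set already differed by at most 0.665%, so repeating the step could hardly move the medians. It therefore cannot decide whether the authors' normalization is a cause. Cells with the profile of the MEF of that set, which would bring all its abundant transcripts, are argued against: beside median shares of 7.28 and 8.30% of the MEF level over 44 such transcripts, 18.18% of them (95% exact interval 8.19 to 32.7%) lay more than 10-fold under these in both lines, such as Ptn (0.215 and 0.416%) and Eln (0.272 and 0.427%), while Thbs1 lay at 68.3 and 61.6%. Fibroblasts in another state are still a candidate explanation, since the labels place CiPSC, and ESC too, on feeder layers of treated MEF. Of the transcripts, 25% (13.2 to 40.3%) lay more than 3-fold under the median share in both lines. A share of 25% or more was set in advance to argue against fibroblasts, and the value lies exactly at that bound. The interval, which was not part of the bound, reaches well under it and leaves this undecided. No difference of the lines themselves was tested.

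The third pattern is that genes called between CiPSC and ESC read low in R1 and less so in TT2. Genes chosen as higher in CiPSC without set 2 had a median difference of -0.1794 there (64 genes), against 1.80, 1.49 and 1.03 in sets 1, 3 and 5 for genes chosen the same way without each, though these rest on 7, 11 and 33 genes. The choice without set 2 used R1 as the only ESC line, while the other choices still used TT2, so they are not fully alike. Compression by the separate normalization of set 2 is argued against, since the spread of CiPSC minus somatic differences there was 0.9222 times the median of the other sets. A difference of strain or line between R1 and TT2 is consistent with these values, but TT2 is 1 sample in 1 set, so other differences of that set stay open.

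Counts were compared with other splits of the same samples within their sets. For CiPSC against somatic, 1 of 100 splits, the real one, gave 4624 calls or more. The highest other gave 2955, with MEF3 exchanged for the CiPSC control line. The share, 0.01, is under the 5% bound set in advance and argues against chance. It is also the smallest that 100 splits can give. For ESC against somatic, 1 of 64 splits gave 4838 or more. The highest other, 3668, exchanged the groups in every set while leaving MAF and ADSC in place. Here the share, 0.0156, is likewise under that bound and the smallest that 64 splits can give. For CiPSC against ESC, 3 of 100 splits gave 5 or more, a share under the 5% bound set in advance. With ESC2 and MNF CiPS1 exchanged the count was 75, and a split with many times the real count points to a structure of the samples. At an unadjusted p under 0.05 limma passed 819 of 16497 genes, where chance alone gives 825. The share therefore does not exclude chance for these 5 genes. For CiPSC by origin the 16 splits are too few for a share under 0.05; the real value was 0, 16 of 16 splits gave as many and the highest other gave 10.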

How the results depend on the processing

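Genes measured in all 5 sets, leaving out the CiPSC lines of set 3, day 12 as reference, the floor of 16 (time course and set 5 bounds), lists over the same genes and time course genes chosen without set 5 were chosen only after results were seen; the other alternatives were fixed before. The counts of CiPSC and ESC against somatic samples stayed within 1.5 times under every alternative run except the replicate block, and without a set term they were 4046 (1654 higher, 2392 lower) and 3420. With the replicate block, ESC against somatic gave 862 calls (233 higher, 629 lower) from 3 MEF and 3 ESC samples, but the numbers do not pair samples: residuals of MEF and ESC with the same number correlated at 0.453, -0.290 and 0.176. CiPSC against ESC gave 2 calls with no set term, 1 with only sets that hold both groups, 1, 42, 0 and 1 without sets 1, 2, 3 and 4, 51 with R1 as the only ESC line and 2 without the CiPSC lines of set 3, 1 of them shared, and 5 without set 5 (3 higher, 2 lower, 2 shared); the cause was not tested beyond the weighing of R1 and TT2. OSKM iPSC against ESC gave 0 with only sets that hold both groups, 1, 0 and 1 without sets 1, 2 and 3 and 0 with the replicate block, and CiPSC against OSKM iPSC gave 1 without set 1. SKM-FSK iPSC against somatic gave 3917 with no set term (3108 higher, 809 lower) and 7257 with only the set that holds both groups, and against ESC 0 with the lowest 25% of genes left out, no set term or genes measured in all 5 sets, 2 without set 2 and 1349 with only the set that holds both groups, where 4 samples leave 1 residual degree of freedom per gene. CiPSC without T gave 1 without set 2. Reversed were Iqcg (1.219 with no set term) and the primed pluripotency list without T (mean -0.08735 without set 2). Of the named genes under all alternatives, 2798 values kept direction and side of the threshold, 103 lost a call and 19 gained 1, and of list values 2010, 79 and 14, with 23 time course medians that moved. Of 59 list calls 26 held with an estimated correlation. The time course count of 4599 at day 32 was 1443 against day 12, where the reference is a treated sample. With 1 sample left out the counts ranged from 4216 to 4778 for CiPSC against somatic, 4433 to 4941 for ESC against somatic, 0 to 51 for CiPSC against ESC, 0 to 8 for OSKM iPSC against ESC, 0 to 1 for CiPSC against OSKM iPSC, 1079 to 3671 for SKM-FSK iPSC against somatic, 1 to 1 for SKM-FSK iPSC against ESC, 0 to 1 for CiPSC by origin and 0 to 1 for CiPSC without T; a lone sample is then assumed to vary like the other groups. SKM-FSK iPSC without MEF2 (against somatic), without ESC4 (against ESC) or without set 4 gave no value. For causes not named the cause was not tested. Signal over background limits set 5 most, where 12.8 to 13.7% of values lie under 10.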

Other observations

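All of the values below were looked at only after the data were seen, and no test was run on them. Genes of the fibroblast list differed in course. The contractile genes Tagln and Acta2 read 64.0 and 74.9 at day 12 against 5806 and 6495 in MEF3 and 1316 and 7978 in MEF2 of set 4. The matrix genes Lum and Dcn read 18915 and 53171 at day 12 against 81.3 and 8278 in MEF3. In MEF2 they read 38002 and 62827, but the sets were normalized separately, with median intensities of 348 in MEF2 and 110 at day 12. These values cannot tell whether the genes rose over MEF other than MEF3. In the CiPSC control line Lum, Dcn, Tagln and Acta2 read 9.7, 127.5, 49.9 and 335.5.

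Nicotinic receptor gene Chrna9 read 0.2 in MEF3, 53.8, 3881 and 8862 at days 12, 20 and 32, and 4.8 in the CiPSC control line, and Rgs3, a regulator of G protein signalling, read 89.3, 194 and 2835 on those days and 3.7 in that line. The cell cycle gene Ccnb2 read 64.0, 99.5 and 1357 at days 12, 20 and 32 and 1049 in the CiPSC control line. Of 2052 genes bright in every sample of sets 3 and 4, 4 read in MEF3 alone with the rest of set 5 at the floor. For the MEF of set 3 the number was 0 of 4751 genes bright in set 4. For the MEF of set 4 it was 1 of 2084 genes bright in set 3, so the genes compared differ by set.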
